A study of Homo sapiens with 113 samples.

How the data were processed

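RNA was measured in extracellular vesicles (EVs, the membrane particles that cells shed) from stimulated whole saliva of human donors. Per the labels' protocols, cells were spun out before storage, the saliva was diluted and passed through a syringe filter, and vesicles and their RNA were taken up with the ExoLution platform. The RNA was treated with DNase, ERCC spike-ins (a set of 92 synthetic RNAs) were added, and random-primed long-RNA libraries were sequenced. The series' design text also speaks of exome sequencing, and the extract protocol describes total RNA libraries. The labels put the 113 libraries in 6 groups. Of these, 24 are labelled SSA_Pos and 47 SSA_Neg, taken here as the Sjögren groups because every other label ends in NonSjogren or names another disease. SSA is the usual name of the Ro autoantigen in this field, which the labels do not spell out. The others are 16 Sicca (dryness symptoms without Sjögren's disease), 16 Healthy, 5 Rheumatoid_Arthritis and 5 Lupus libraries. The labels do not say that each library came from its own donor, so p-values measure the spread between these libraries.

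The deposited table holds estimated counts per gene that need not be whole: 71.9% of the values were 0, and 0% of the others equalled a whole number exactly. They were made with STAR 2.7.9a and Salmon 1.9.0 on GRCh38, per the submitters' processing notes, which give no role or order. That the counts were scaled for transcript length is known from the table's name alone. The annotation release and the counting strand are not given in the sources used here, so reads of a gene and its antisense partner, or of near-identical copies such as the salivary amylase genes or the genes for proline-rich proteins, cannot be told apart. The table has 61644 rows, of which 92 are spike-ins and 61552 genes; 61544 gene identifiers were matched to a name through a gene name table or GENCODE 29, and 8 were not. Coordinates are those of GENCODE 29 on GRCh38. XIST, TSIX and Y-linked genes, 557 rows, were left out of all tests because the donors are human. They held at most 0.796% of a library's counts. Of the other rows, 47144 had a count in at least 1 library. No 2 libraries were duplicates: the highest Pearson correlation of log2 values between any pair was 0.913.

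The sample titles carry prefixes that split the libraries into series, whose meaning (cohort, site or batch) the labels do not give. The first title series holds 9 SSA_Pos, 2 SSA_Neg and 9 Healthy libraries; the second holds 15 SSA_Pos, 9 SSA_Neg, 16 Sicca and 7 Healthy; the third holds 36 SSA_Neg libraries and nothing else. The 10 Rheumatoid_Arthritis and Lupus titles carry no prefix. Comparisons among SSA_Pos, SSA_Neg, Sicca and Healthy used the 67 libraries of the first and second series in 1 fit with title series as a term. Comparisons with Rheumatoid_Arthritis and Lupus used all 113 libraries with group alone, so that group and any batch of those 10 libraries cannot be told apart. The numbers in their titles fall in a gap of those of the first series, so the 2 sets may have been numbered together; the labels do not say whether they were made together. With the first series as the only other libraries edgeR called 0, 1 and 0 genes, against 230, 341 and 1320. The third series was compared with the other SSA_Neg libraries in a fit of the 47.

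The estimated counts were rounded to whole numbers. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 18182 genes in the fit of 67 libraries, 25045 in that of 113, 17913 for the third series and 18466 for the test of whether the SSA_Pos effect differs between series. Libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood F test (robust, with the method from before edgeR 4) in R 4.3.3. A gene is called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. All tests are two-sided. Adjusted p-values given for genes are edgeR's unless another tool is named, and ± after a log2 fold change is its standard error. Called genes are described as sparse where neither side had 10 counts in at least 50% of its libraries. The fitted fold of a gene with almost no counts on one side rests on the prior count, so for those genes the numbers of libraries with at least 10 counts are given in its place.

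Before the data were examined, 22 gene lists were fixed: interferon-stimulated, interferon-gamma response, MHC class I presentation, NF-kB inflammatory, mucosal antimicrobial, unfolded protein response, vesicle marker, Sjögren-associated, mitochondrially encoded, ribosomal protein and nuclear respiratory chain genes, and markers of neutrophils, monocytes and macrophages, B cells, plasma cells, T and NK cells, serous acinar, mucous acinar, duct and squamous epithelial cells, erythrocytes and platelets. The libraries are bulk, so a marker list names genes and not cells. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 264 tests, and again with a correlation estimated from the residuals. Of the 82 list tests that passed, 2 passed with the estimated correlation; both are of the interferon-stimulated list. A score per library, the mean log2 CPM of a list (prior count 2), was compared by a permutation test within title series with 100000 resamples, or by exact enumeration, adjusted over 220 tests; this score test was chosen after the data had been seen. Total counts, genes with a count of at least 1 and shares of counts were compared in the same way over 80 tests. Tests ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

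Genes named in the text follow a rule fixed before the data were examined: the called genes with the smallest adjusted p per direction (10 in the 4 main comparisons, 5 in the others) that go the same way in both title series, without clone, pseudogene and small RNA names; 22 fixed genes; and up to 4 members of each list that passed camera. From that set the text names those that are best known or best measured; the full set is larger than the text.

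Each comparison was repeated with DESeq2 1.42.0 size factors, DESeq2's Wald test, limma voom with sample weights, no filter, a stricter filter (10 counts in at least 50% of libraries), all 113 libraries, the title prefix as the term, the second series alone, without shallow libraries, and, for the groups of 5, with each replicate left out. With replicates left out, these were added after the data had been seen: the gene lists, and the counts over the genes of the fit with all libraries. The plan named edgeR's quasi-likelihood fit without saying which of its 2 methods. The package's default is the newer one, of edgeR 4. The first script used the older one, and it was kept only after the counts of both had been seen, because a trial with relabelled groups still gave many more calls with the newer method. The choice is thus not one made before seeing the data; counts with the newer method are in the sensitivity section, and relabelled groups with both are in the closing section. Added after the data had been seen were the quasi-likelihood method of edgeR 4, the log2 spike-in share or the number of genes detected as a covariate, and the third-series test without 3 gene models inside 18S rRNA genes. Groups were also relabelled within title series, 80 or 100 times (60 with voom and with the edgeR 4 method, both added after the data had been seen), and refitted.

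Totals per library ran from 1.82 to 384 M (mega) gene counts (median 22.5 M). Counts were simulated for the 67 libraries with their real sizes and each gene's mean over all of them, and genes were changed in SSA_Pos. In SSA_Pos against Healthy, over 17584 genes, the edgeR test recovered 4 of 100 genes changed 2-fold and 23 of 100 changed 4-fold, and 10 of its 37 calls were false. DESeq2 recovered 14 and 45 and made 73 false calls of 132; voom recovered 4 and 18 with 0 false calls of 22. The same was done for all 113 libraries, with genes changed in Lupus. In Lupus against Healthy, over 24379 genes, edgeR recovered 1 and 3, and 20 of its 24 calls were false. DESeq2 made 565 false calls of 587 and voom 3 of 7. The score test found 43 of 50 simulated shifts of 1 SD and gave a p under 0.05 in 10 of 150 unchanged scores.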

Results

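The study profiled long RNA in saliva extracellular vesicles (EVs) to look for markers of Sjögren's disease, an autoimmune disease of the salivary and tear glands. The libraries comprised 24 SSA_Pos and 47 SSA_Neg libraries from Sjögren's disease, 16 Sicca libraries, 16 Healthy libraries and, as other autoimmune diseases, 5 Rheumatoid_Arthritis and 5 Lupus libraries. Median totals were 25.8 M (mega) gene counts in SSA_Pos (8.91 to 201), 24.5 in SSA_Neg (9.16 to 384), 17.5 in Sicca (6.24 to 269), 37.9 in Healthy (7.41 to 62.2), 23 in Rheumatoid_Arthritis (7.98 to 25.4) and 8.59 in Lupus (1.82 to 41.8).

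Among the fixed gene lists, levels in the 67 libraries of the first and second title series were highest for genes of neutrophils, the ribosome and squamous epithelium. The neutrophil list, which holds genes such as S100A8 and S100A9, averaged 8.57 ± 0.78 log2 CPM (SD, n = 67), the ribosomal protein list 8.25 ± 0.77 and the squamous epithelial list 7.71 ± 1.38. Serous acinar genes, which encode secreted proteins of the salivary glands, averaged 5.29 ± 1.77 and mucous acinar genes 5.59 ± 1.31. The interferon-stimulated list averaged 5.23 ± 1.64 and the vesicle marker list 6.60 ± 0.42. B cell genes (-2.06 ± 1.74), T and NK cell genes (-1.81 ± 1.48), mitochondrially encoded genes (-1.81 ± 1.53), erythrocyte genes (-1.50 ± 2.20) and platelet genes (-2.36 ± 1.42) lay near the floor of measurement. Libraries of Sjögren's disease held more detected genes than the others, 16835 ± 2384 (SD, n = 35) against 14828 ± 2276 (n = 32; permutation test, adjusted p = 0.016). Their log2 spike-in share was lower, -0.09 ± 1.84 against 1.17 ± 1.30 (permutation test, adjusted p = 0.0406). SSA_Pos and Sicca differed in the same measures (permutation tests, adjusted p = 0.0372 for each). Averages were 16992 ± 2554 (n = 24) against 15210 ± 2292 (n = 16) genes, and log2 spike-in shares of -0.41 ± 1.77 against 1.37 ± 1.33. All Sicca libraries are in the second title series and the tests work within series. They therefore compared Sicca with only the 15 SSA_Pos libraries of that series, which held 17561 ± 1333 genes. Between SSA_Pos and Healthy the adjusted p was 0.0825 for genes detected and 0.127 for the log2 spike-in share. The log2 spike-in share and the number of genes were also related after the mean of each group within its title series was subtracted from both. Across the 67 libraries these values fell on a steep inverse relation, with r = -0.86 and rho = -0.81 (permutation p = 1e-05 for each, the smallest possible, and adjusted p of r = 6e-05 over 6 relations). It held within the first (r = -0.89, n = 20) and second series (r = -0.83, n = 47) and without the 2 farthest libraries (r = -0.82).

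**Figure D1:**
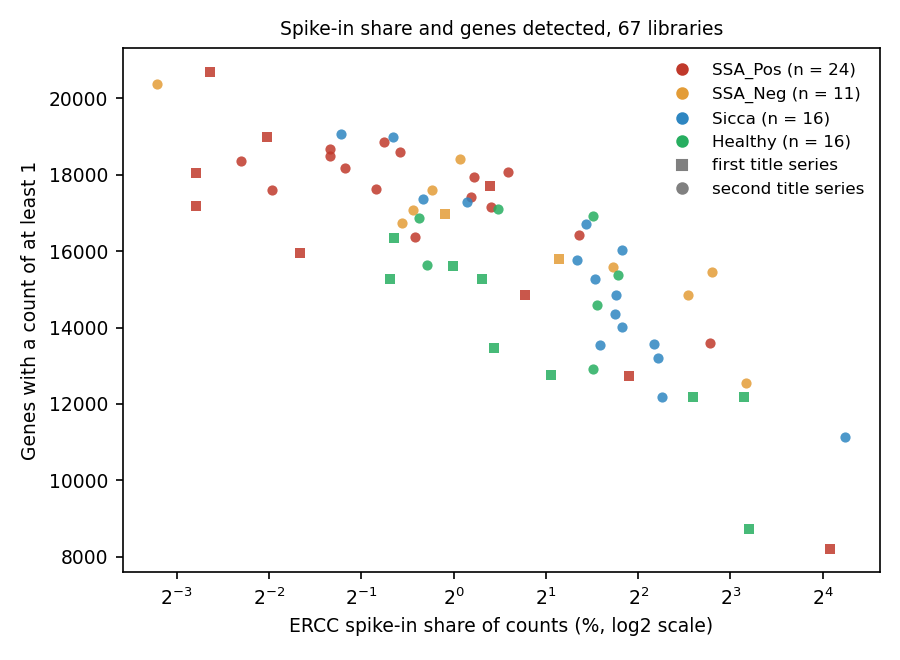
Each point is 1 of the 67 libraries of the first (squares) and second (circles) title series, with the ERCC spike-in share of counts (%, log2 scale) on the x axis and the number of genes with a count of at least 1 on the y axis, coloured by group. Libraries with a larger spike-in share had fewer genes detected. The points are values as measured, while r = -0.86 with the log2 share was taken after subtracting the mean of each group within its title series.

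The first question was how vesicle RNA of SSA_Pos donors differed from that of Healthy donors. Interferon-stimulated genes, the antiviral genes that cells switch on after interferon signalling, rose together: 21 of 42 were called higher over all genes tested (32 adjusted over the list alone), all 42 had a positive fold change, and the median log2 fold change was 2.01 (camera adjusted p = 1.56e-43, and adjusted p = 0.036 with an estimated correlation). The IFIT genes, which encode proteins that bind foreign RNA, lie side by side on chromosome 10 (GRCh38): IFIT3 (ENSG00000119917, 89327894 to 89340971) rose by 2.89 ± 0.42 (adjusted p = 3.54e-05), IFIT1 (ENSG00000185745, 89392546 to 89406486) by 3.01 ± 0.47 (adjusted p = 0.000106) and IFIT2 (ENSG00000119922, 89283694 to 89309276) by 2.12 ± 0.35 (adjusted p = 0.000303). RSAD2 (3.86 ± 0.74), LY6E (3.87 ± 0.75), OAS2 (3.57 ± 0.70), OAS3 (2.86 ± 0.54), OASL (2.96 ± 0.56), IFI6 (3.40 ± 0.74), MX1 (1.89 ± 0.43) and the ubiquitin-like ISG15 (3.10 ± 0.64, adjusted p = 0.00765; chromosome 1, 1001138 to 1014540) were also called. IFI44L, at 3.49 ± 0.97, was not (adjusted p = 0.0788). The score of the list averaged 6.62 ± 1.53 log2 CPM in SSA_Pos (SD, n = 24) and 4.28 ± 0.85 in Healthy (n = 16), a difference of 2.34 ± 0.43 (permutation p = 1e-05, the smallest possible; adjusted p = 0.0022).

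That difference was found within each title series. In the first, SSA_Pos averaged 6.93 ± 1.97 (n = 9) and Healthy 4.0 ± 0.89 (n = 9; exact permutation p = 0.0016), and 7 of 9 SSA_Pos libraries lay above the highest Healthy library. In the second, SSA_Pos averaged 6.44 ± 1.24 (n = 15) and Healthy 4.64 ± 0.71 (n = 7; exact permutation p = 0.0026), with 9 of 15 above the highest. With the second series alone, 0 interferon-stimulated genes were called over all genes by edgeR, against 16 adjusted over the list alone, and the median stayed at 1.59.

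**Figure D2:**
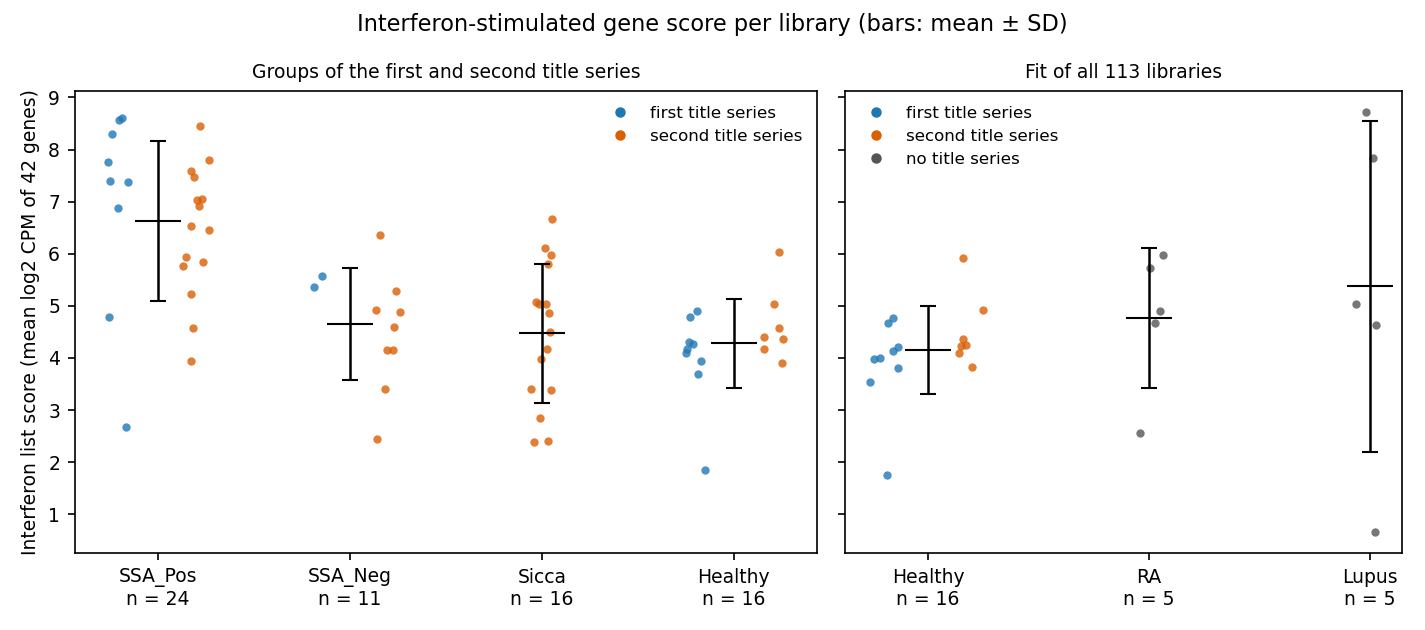
The y axis gives the score of the interferon-stimulated list per library (mean log2 CPM of 42 genes); each point is 1 library, coloured by title series, and bars are the mean ± SD of each group, for the 67 libraries of the first and second series and, separately, for Healthy, Rheumatoid_Arthritis (RA) and Lupus as scaled with the libraries of all groups. SSA_Pos libraries averaged 6.62 against 4.65 in SSA_Neg, 4.48 in Sicca and 4.28 in Healthy.

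Genes that respond to interferon gamma had a median log2 fold change of 0.79 between SSA_Pos and Healthy, and 3 of 22 were called higher (6 adjusted over the list alone; camera adjusted p = 1.14e-06, adjusted p = 0.502 with an estimated correlation). The guanylate-binding proteins GBP1 (1.88 ± 0.40, adjusted p = 0.00849) and GBP5 (2.28 ± 0.54, adjusted p = 0.0191) rose. CXCL11, a chemokine that attracts activated T cells, had at least 10 counts in 10 of 24 SSA_Pos libraries and 0 of 16 Healthy libraries (adjusted p = 0.0103). CD3D, a chain of the T cell receptor complex, had them in 8 of 24 and 0 of 16 (adjusted p = 0.0448). The T and NK cell list passed camera with a median of 0.75 (adjusted p = 0.00642, adjusted p = 0.701 with an estimated correlation), and not with the spike-in share as a covariate (adjusted p = 0.109). OTOF, which encodes a calcium sensor of vesicle fusion, reached 10 counts in 14 of 24 and 0 of 16 (adjusted p = 0.000622). TMEM123 also rose, by 1.69 ± 0.29 (adjusted p = 0.000472). TNFSF13B, the B cell survival factor BAFF, was at 1.13 ± 0.34 without a call (adjusted p = 0.113).

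Serous acinar genes were lower in SSA_Pos than in Healthy libraries as a list, with a median log2 fold change of -1.63 and 28 of 28 negative (camera adjusted p = 1.44e-17, adjusted p = 0.305 with an estimated correlation). None of the 28 was called by edgeR over all genes, and 17 were adjusted over the list alone; 8 were called by DESeq2 and 2 by voom. Of the members named here, the smallest adjusted p-values were those of genes of proline-rich saliva proteins, PRB2 (-1.89 ± 0.51, adjusted p = 0.0588), PRH1 (-2.20 ± 0.63, adjusted p = 0.0901) and PRB1 (-1.79 ± 0.56, adjusted p = 0.153). STATH (-1.57 ± 0.52), the amylase gene AMY1A (-2.16 ± 0.77) and the water channel AQP5 (-0.82 ± 0.51) had adjusted p-values of 0.209 or more, up to 0.746. The score averaged 5.06 ± 1.23 in SSA_Pos (n = 24) and 6.0 ± 1.91 in Healthy (n = 16; permutation p = 0.0529, adjusted p = 0.299).

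Over all 18182 genes, 102 were higher and 11 lower in SSA_Pos than in Healthy, and 58 of these were sparse. The lower genes included VPS9D1 (-2.30 ± 0.53, adjusted p = 0.0128), the endothelin-processing enzyme ECE1 (-1.55 ± 0.36, adjusted p = 0.0146) and the cytoskeletal linker TLN1 (-1.19 ± 0.31, adjusted p = 0.0441). The neutrophil gene S100A9 stood at -0.14 ± 0.22 (adjusted p = 0.974). Ribosomal protein genes (median -0.27, camera adjusted p = 7.76e-18) and nuclear respiratory chain genes (-0.23, adjusted p = 3.02e-06) passed as lists with 0 members called by edgeR over all genes. Adjusted p was 0.701 and 0.67 with an estimated correlation, and 0.688 and 0.22 with the spike-in share as a covariate. Squamous epithelial genes passed at a median of -0.07 (adjusted p = 0.00248, adjusted p = 0.861 with an estimated correlation), and their median was 0.34 in the second series alone. DESeq2 size factors gave 83 higher and 33 lower genes and moved the median of all genes from 0.04 to -0.14. In the second series alone 4 genes were called, all lower; with the number of genes detected as a covariate 41 were.

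SSA_Pos and SSA_Neg libraries were compared to see what goes with SSA status within Sjögren's disease. The same interferon list differed, with a median log2 fold change of 1.76 and all 42 genes positive (camera adjusted p = 1.99e-38, adjusted p = 0.036 with an estimated correlation). IFIT1 (2.84 ± 0.55, adjusted p = 0.0175) and IFIT3 (2.35 ± 0.48, adjusted p = 0.039) were called over all genes, and 29 members were adjusted over the list alone. In all 3 genes were called, with 863 at an unadjusted p under 0.05. That number depended on the model: edgeR called 0 with the title prefix, the second series alone or the spike-in share (787, 848 and 759 at an unadjusted p under 0.05), and voom called 0 higher and 3 lower. DESeq2 called 67. Of 80 labellings that shuffled SSA_Pos, SSA_Neg, Sicca and Healthy together, the real one included, 32 called at least as many (highest other 52). MX1, at 2.37 ± 0.51, narrowly missed (adjusted p = 0.0536). The score averaged 6.62 ± 1.53 in SSA_Pos (n = 24) and 4.65 ± 1.08 in SSA_Neg (n = 11), a difference of 1.86 ± 0.52 (permutation p = 0.0011, adjusted p = 0.055). It was 1.08 ± 0.40 with the monocyte and macrophage score as a covariate (permutation p = 0.0108). The difference between SSA_Neg and Healthy (4.28 ± 0.85, n = 16) was 0.31 ± 0.41 (permutation p = 0.458). This covers only the SSA_Neg libraries of the first and second title series. Scaled with the libraries of all groups, the 36 SSA_Neg libraries of the third series averaged 5.05 ± 1.12 and Healthy 4.16 ± 0.85. Group and title series cannot be told apart in that pair of values.

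The third called gene between SSA_Pos and SSA_Neg was LAMC1, a laminin chain of basement membranes, lower in SSA_Pos (-5.41 ± 1.03, adjusted p = 0.0175), but a single library carried 91.9% of its summed CPM. Genes of interferon gamma response (median 0.88, adjusted p = 5.64e-06), MHC class I presentation (0.46, adjusted p = 0.0184), T and NK cells (1.04, adjusted p = 0.00526), squamous epithelium (0.53, adjusted p = 0.0171) and the Sjögren-associated list (0.51, adjusted p = 0.0425) were higher as lists by camera. GBP1 stood at 1.67 ± 0.46 and TNFSF13B at 1.38 ± 0.40, both without a call. Ribosomal protein (-0.37, adjusted p = 4.85e-32), nuclear respiratory chain (-0.33, adjusted p = 1.26e-08) and serous acinar genes (-0.56, adjusted p = 0.00425) were lower as lists. None of these 8 lists passed with an estimated correlation (adjusted p from 0.502 to 0.892). The MHC class I list missed with DESeq2 size factors (adjusted p = 0.0816), and the serous acinar median was 0.06 in the second series alone.

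**Figure D3:**
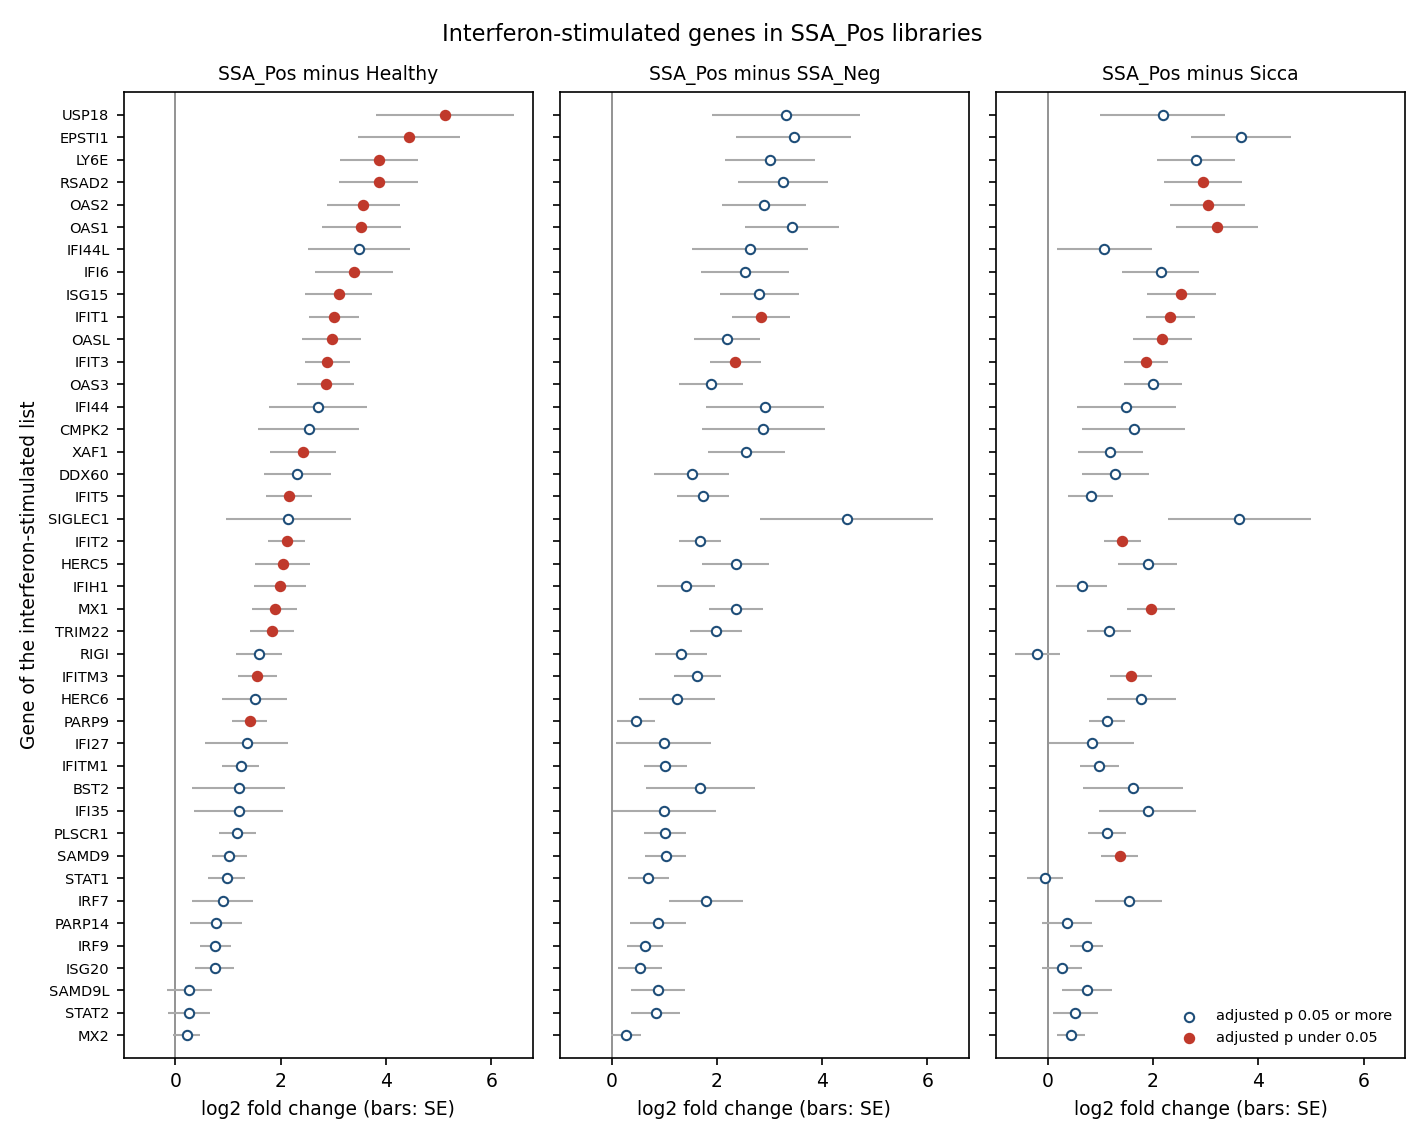
Points are the log2 fold changes (x axis, bars: standard error) of the 42 interferon-stimulated genes (y axis). Panels from left to right show SSA_Pos against Healthy, SSA_Neg and Sicca. Points are filled red where the adjusted p over all genes was under 0.05. All 42 genes lie to the right of 0 against Healthy and SSA_Neg, and 40 against Sicca, with 21, 2 and 11 called against Healthy, SSA_Neg and Sicca.

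Sicca donors have dryness without Sjögren's disease, so SSA_Pos against Sicca asks what marks the disease among people with dryness. Interferon-stimulated genes were higher here too: 11 of 42 were called higher (24 adjusted over the list alone), with a median of 1.52 (camera adjusted p = 3.1e-26, adjusted p = 0.205 with an estimated correlation). IFIT1 (2.33 ± 0.47, adjusted p = 0.0192), OAS2 (3.04 ± 0.70, adjusted p = 0.0237), MX1 (1.96 ± 0.45, adjusted p = 0.023), IFIT3 (1.87 ± 0.42, adjusted p = 0.0212) and ISG15 (2.54 ± 0.65, adjusted p = 0.0456) rose. The score averaged 4.48 ± 1.33 in Sicca (n = 16), all in the second title series. It lay 1.96 ± 0.53 below SSA_Pos of that series (6.44 ± 1.24, n = 15, permutation p = 0.00024, adjusted p = 0.0176). It differed by 1.19 ± 0.51 with the spike-in share as a covariate (permutation p = 0.0276) and by 0.93 ± 0.45 with the monocyte and macrophage score (permutation p = 0.047).

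In all, 72 genes were higher and 23 lower in SSA_Pos than in Sicca, and 43 of the 95 were sparse. ORC2, a subunit of the complex that starts DNA replication, rose by 4.42 ± 0.96, and DPYSL4 had at least 10 counts in 13 of 24 SSA_Pos and 0 of 16 Sicca libraries (adjusted p = 0.0192 for each). PLCG2, a phospholipase of B cell and myeloid receptor signalling (-1.85 ± 0.41, adjusted p = 0.0192), the nonsense-mediated decay helicase UPF1 (-1.98 ± 0.45, adjusted p = 0.0224) and the cohesin loader MAU2 (-2.05 ± 0.45, adjusted p = 0.0192) fell. Gland lists were lower by camera: serous acinar (median -0.71, adjusted p = 5.38e-07), mucous acinar (-0.60, adjusted p = 0.00207) and duct genes (-0.39, adjusted p = 7.57e-05). None of the 3 passed with an estimated correlation (adjusted p = 0.67, 0.502 and 0.282), nor duct genes with the spike-in share as a covariate (0.16). Within the second title series, the scores per library were not lower in SSA_Pos for the serous and mucous lists. The serous score averaged 5.22 in SSA_Pos (n = 15) and 5.14 in Sicca (n = 16), and the mucous score 5.81 and 5.76. The duct score was lower in SSA_Pos, at 4.97 against 5.15. PIP (-1.42 ± 0.48), DMBT1 (-1.55 ± 0.51), ZG16B (-1.04 ± 0.41), AGR2 (-1.11 ± 0.41) and MUC7 (-1.14 ± 0.47), which salivary and mucous glands express, had no call.

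Ribosomal protein genes (-0.41, adjusted p = 5.49e-33; all 78 negative, with RPL3 at -0.52 ± 0.21 and RPL13 at -0.56 ± 0.22) and nuclear respiratory chain genes (-0.33, adjusted p = 5.65e-05) were also lower in SSA_Pos than in Sicca as lists, while interferon gamma (0.88, adjusted p = 0.000162) and monocyte and macrophage genes (0.90, adjusted p = 0.0034; FCN1 1.13 ± 0.40) were higher. No list of this comparison passed with an estimated correlation (adjusted p from 0.205 to 0.701). With the spike-in share as a covariate 12 genes were called in place of 95, and the ribosomal (adjusted p = 0.667), respiratory chain (0.796) and monocyte lists (0.237) no longer passed. The direction of the calls also depended on scaling, since DESeq2 size factors gave 92 higher and 179 lower genes.

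Sjögren's disease was set against the other groups of the first and second series. Gene fold changes compare the mean of SSA_Pos and SSA_Neg with the mean of Healthy and Sicca, each group weighted equally. The score pools libraries, 24 of 35 being SSA_Pos, so the 2 differ in what they compare. The interferon list was higher, with a median of 0.71 and 41 of 42 positive; 2 members were called (16 adjusted over the list alone; camera adjusted p = 1.07e-18, adjusted p = 0.305 with an estimated correlation). Its score averaged 6.0 ± 1.67 (n = 35) against 4.38 ± 1.10 (n = 32; difference 1.61 ± 0.35, permutation test, adjusted p = 0.0022). PARP9 (1.03 ± 0.25, adjusted p = 0.0347) and IFIT3 (1.2 ± 0.30, adjusted p = 0.047) were the called members, and OAS3 (1.49 ± 0.38), OAS2 (1.85 ± 0.48) and ISG15 (1.41 ± 0.45) were not. TMEM123 rose by 0.99 ± 0.21 (adjusted p = 0.0144) and the collagen receptor MRC2 by 3.41 ± 0.71 (adjusted p = 0.0128). LRRC56 had at least 10 counts in 11 of 35 Sjögren libraries and 0 of 32 others (adjusted p = 0.000176), and CXCL11 in 13 of 35 and 2 of 32 (adjusted p = 0.0245).

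Of the 52 genes called between Sjögren and other libraries, 45 were higher, 7 lower and 39 sparse. VPS9D1 (-1.74 ± 0.41, adjusted p = 0.0319) and the epithelial sorting adaptor AP1M2 (-1.66 ± 0.40, adjusted p = 0.0378) fell. Serous acinar genes had a median of -0.77 with 28 of 28 negative (camera adjusted p = 2.92e-12), and PRB2 stood at -1.02 ± 0.42 and STATH at -0.87 ± 0.44 without a call. The duct (-0.24, adjusted p = 0.00554), ribosomal protein (-0.16, adjusted p = 1.32e-10), respiratory chain (-0.13, adjusted p = 0.024) and squamous lists (-0.09, adjusted p = 0.000868) were lower and the interferon gamma list higher (0.39, adjusted p = 0.00318). None of these passed with an estimated correlation (adjusted p from 0.433 to 0.867). With the spike-in share as a covariate the ribosomal list turned to a median of 0.06. DESeq2 size factors gave 44 higher and 31 lower genes, and the stricter filter left 0 calls by edgeR. With the usual filter 1493 genes had an unadjusted p under 0.05, DESeq2 called 280, and voom 102 higher and 11 lower.

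SSA_Neg and Healthy libraries differed in 8 genes, all higher, of which 7 were sparse, with 872 at an unadjusted p under 0.05. The title prefix and the second series alone left 0 by edgeR (912 and 1233 at an unadjusted p under 0.05) and voom called 0 (1113). The stricter filter left 1, either covariate 2, and DESeq2 called 102. Of 80 labellings that shuffled SSA_Pos, SSA_Neg, Sicca and Healthy together, the real one included, 9 called at least as many (highest other 26). CBARP and RASL11A each had at least 10 counts in 5 of 11 SSA_Neg and 0 of 16 Healthy libraries (adjusted p = 0.0207 and 0.0455), and CXCL11 in 3 of 11 and 0 of 16 (adjusted p = 0.0455). LAMC1 again rested on a single library, with 94.3% of its summed CPM. Serous acinar (median -1.14, camera adjusted p = 6.32e-07; PRB2 -1.31 ± 0.65, STATH -1.22 ± 0.67), squamous (-0.56, adjusted p = 8.42e-08; KRT13 -0.87 ± 0.56) and mitochondrially encoded genes (-0.65, adjusted p = 0.023) were lower as lists, with 0 members called by edgeR over all genes. None passed with an estimated correlation (adjusted p from 0.67 to 0.708), and the squamous median was 0.11 in the second series alone. ISG15 stood at 0.29 ± 0.68 without a call.

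Between SSA_Neg and Sicca 6 genes were called, all higher and all sparse. They included WASH5P, with at least 10 counts in 5 of 11 SSA_Neg and 1 of 16 Sicca libraries (adjusted p = 0.0193), and the receptor kinase MST1R, in 3 of 11 and 1 of 16 (adjusted p = 0.027). The direction of calls depended on the tool. DESeq2's Wald test called 50 higher and 50 lower, the edgeR 4 method 208 and 216, and the second series alone 19 and 1. Voom and the stricter filter called 0, with 1257 and 549 genes at an unadjusted p under 0.05. Mucous acinar (median -0.43, camera adjusted p = 0.0202; AGR2 -0.69 ± 0.49), duct (-0.32, adjusted p = 0.0397) and serous acinar genes (-0.11, adjusted p = 0.0489; DMBT1 -1.25 ± 0.62) were lower as lists. None passed with an estimated correlation (adjusted p from 0.684 to 0.892). The fold changes of SSA_Pos against Healthy and of SSA_Neg against Sicca, which share no library, had a Spearman correlation of 0.018 across genes with edgeR and 0.203 with voom; genes are not independent replicates.

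Sicca and Healthy libraries differed in 50 genes, 31 higher and 19 lower, of which 48 were sparse. In the second series alone, which holds all Sicca libraries, 0 were higher and 11 lower. Voom and the stricter filter called 0, with 854 of 18182 and 669 of 13219 genes at an unadjusted p under 0.05, both close to 1 in 20. DESeq2 called 114 higher and 52 lower. The immunoglobulin segment IGKV3-20 had at least 10 counts in 5 of 16 Sicca and 0 of 16 Healthy libraries (adjusted p = 0.0151), PCDHAC1 in 6 and 0 (adjusted p = 0.00848), and LYPD1 in 0 and 5 (adjusted p = 0.00848). Serous acinar genes were lower in Sicca too (median -1.11, camera adjusted p = 0.00425; PRB1 -1.47 ± 0.65, AMY1C -1.63 ± 0.67) while mucous acinar genes were higher (0.70, adjusted p = 0.00491; AGR2 1.2 ± 0.47, MUC5B 0.79 ± 0.43). Interferon-stimulated genes had a median of 0.54 (adjusted p = 0.000392; RIGI 1.78 ± 0.50), 0 called by edgeR over all genes and 1 adjusted over the list alone. Their scores averaged 4.48 ± 1.33 in Sicca and 4.28 ± 0.85 in Healthy (n = 16 each). The test within title series compared Sicca with only the 7 Healthy libraries of the second series, at 4.64 ± 0.71 (permutation p = 0.758). Ribosomal protein genes were higher (0.16, adjusted p = 0.00159), and squamous (-0.44, adjusted p = 0.000629), neutrophil (-0.26, adjusted p = 0.00188) and NF-kB genes (-0.23, adjusted p = 0.0244; PTGS2 -0.98 ± 0.32) lower. None passed with an estimated correlation (adjusted p from 0.623 to 0.899). The interferon (adjusted p = 0.777), mucous (0.191), ribosomal (0.437) and squamous lists (0.57) did not pass in the second series alone.

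Lupus, another disease with an interferon response, was set against Healthy in the fit of all groups. Of 42 interferon-stimulated genes 13 were called higher (28 adjusted over the list alone), with a median of 1.91 (camera adjusted p = 1.78e-18, adjusted p = 0.344 with an estimated correlation). IFIT3 (2.73 ± 0.61, adjusted p = 0.00694), IFIT1 (3.11 ± 0.71, adjusted p = 0.00838), RSAD2 (3.83 ± 0.94, adjusted p = 0.0128), LY6E (4.09 ± 1.01, adjusted p = 0.0131), ISG15 (3.35 ± 0.84, adjusted p = 0.0153) and TMEM123 (2.13 ± 0.42, adjusted p = 0.00564) rose. The score varied widely among the 5 libraries, at 5.38 ± 3.17 against 4.16 ± 0.85 in 16 Healthy libraries (exact permutation p = 0.149). Without Lupus replicate 4 the number called was 0 by edgeR and the median 0.78; without replicate 5 it was 2, and voom called 0 of the list.

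Squamous epithelial (median -1.57, camera adjusted p = 4.71e-19; KRT13 -2.36 ± 0.79), ribosomal protein (-0.65, adjusted p = 1.03e-24; RPL41 -1.36 ± 0.49), duct (-1.0, adjusted p = 0.00029), NF-kB (-0.58, adjusted p = 0.000244), respiratory chain (-0.45, adjusted p = 0.0034) and neutrophil genes (-0.23, adjusted p = 7.44e-08; S100A8 -1.21 ± 0.53) were lower in Lupus as lists. The median of all 25045 genes was -0.30, below that of the neutrophil list. Mitochondrially encoded (1.61, adjusted p = 0.0271), erythrocyte (2.69, adjusted p = 0.00975) and T and NK cell genes (0.56, adjusted p = 0.00526) were higher; CD3D had at least 10 counts in 3 of 5 Lupus and 0 of 16 Healthy libraries (adjusted p = 0.0232). None passed with an estimated correlation (adjusted p from 0.344 to 0.847). The squamous, ribosomal and duct lists passed by camera without each of the 10 Rheumatoid_Arthritis and Lupus libraries in turn, and the others rested on single libraries. Without Lupus replicate 3 neither the neutrophil (median -0.09, adjusted p = 0.501) nor the NF-kB list (-0.45, 0.328) passed. Without replicate 4 the T and NK cell (-1.81, 0.742), erythrocyte (0, 0.484) and respiratory chain lists (-0.45, 0.0794) did not pass. The mitochondrially encoded (-0.53, 0.675) and respiratory chain lists (-0.44, 0.0742) did not without replicate 5, nor the erythrocyte (2.29, 0.104) and mitochondrially encoded lists (1.2, 0.149) without replicate 2. In all, 335 genes were higher and 6 lower, and 316 of the 341 were sparse. Voom called 103 higher and 5 lower, while DESeq2 gave the opposite balance, 134 and 917. With the first series as the only other libraries edgeR called 1.

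Rheumatoid_Arthritis libraries differed from Healthy in 230 genes, 214 higher and 16 lower, of which 194 were sparse. Other tools gave the opposite balance, with 157 higher and 1707 lower by DESeq2 and 7 and 15 by voom. IL5RA, a cytokine receptor chain of eosinophils, had at least 10 counts in 3 of 5 Rheumatoid_Arthritis and 0 of 16 Healthy libraries (adjusted p = 0.00387). DONSON, a DNA replication factor, had them in 0 of 5 and 16 of 16 (adjusted p = 0.0127), and the non-muscle myosin gene MYH10 in 2 of 5 and 16 of 16 (adjusted p = 0.0223). SNHG26 was called from 1 library. Interferon-stimulated genes had a median of 0.48 with 0 called by edgeR (camera adjusted p = 3.22e-05; EPSTI1 2.21 ± 1.12), and the score was 4.77 ± 1.35 against 4.16 ± 0.85 (n = 5 and 16; exact permutation p = 0.238). NF-kB (0.25, adjusted p = 0.016; TNFAIP3 0.87 ± 0.46) and unfolded protein response genes (0.08, adjusted p = 0.0304) were higher as lists, and squamous (-0.82, adjusted p = 0.00374), duct (-0.63, adjusted p = 0.0231) and ribosomal protein genes (-0.52, adjusted p = 3.75e-05; RPS3 -0.91 ± 0.46) lower. The median of all 25045 genes was -0.55, so the medians of the duct and ribosomal lists lie close to it; camera compares test statistics with those of other genes. None passed with an estimated correlation (adjusted p from 0.67 to 0.892). The interferon and ribosomal lists passed by camera without each of the 10 libraries of the 2 diseases in turn. The NF-kB list did not without Rheumatoid_Arthritis replicate 2 (median -0.31, adjusted p = 0.941), 4 (0.19, 0.0728) or 5 (0.10, 0.171) or Lupus replicate 1 (0.09, 0.0802) or 3 (0.09, 0.0777). Duct (-0.52, 0.117 and -0.82, 0.175) and squamous genes (-0.82, 0.0532 and -0.71, 0.155) did not without Rheumatoid_Arthritis replicates 1 and 2. Of these 10 fits the unfolded protein response list passed only in that without Rheumatoid_Arthritis replicate 5, with adjusted p up to 0.177 in the others. The stricter filter and the first series as the only other libraries each left 0 calls by edgeR; 4446 genes had an unadjusted p under 0.05 with all libraries, and 2861 with the first series.

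SSA_Pos was also compared with the mean of Rheumatoid_Arthritis and Lupus, to ask what sets it apart from other autoimmune diseases. Interferon-stimulated genes had a median of 0.73 with 0 called by edgeR and 0 adjusted over the list alone (camera adjusted p = 4.06e-06; OAS2 2.0 ± 0.79, IFITM3 1.19 ± 0.48), and interferon gamma genes one of 0.96 (adjusted p = 0.0318), which did not pass without Lupus replicate 3 (0.311) or Rheumatoid_Arthritis replicate 4 (0.0631). Serous acinar genes were lower (-1.52, adjusted p = 5.75e-19; PRB2 -1.89 ± 0.64, HTN3 -2.29 ± 0.81) with 4 adjusted over the list alone, and squamous genes higher (1.2, adjusted p = 0.000125; SBSN 1.73 ± 0.54, adjusted p = 0.0468). None of these 4 lists passed with an estimated correlation (adjusted p = 0.708 for the interferon-stimulated, 0.847 for the interferon gamma, 0.282 for the serous and 0.786 for the squamous list). The median of all 25045 genes was 0.57, so that of the interferon-stimulated list lies not far above it. DONSON had at least 10 counts in 24 of 24 SSA_Pos and 2 of 10 other libraries (adjusted p = 0.0208), and the cell junction gene AMOTL1 fell by 2.59 ± 0.59 on the log2 scale (adjusted p = 0.0286). The platelet tubulin TUBB1 reached 10 counts in 0 of 24 and 3 of 10 (adjusted p = 0.0248).

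Of the 1320 genes called between SSA_Pos and the pair of other diseases, 1271 were higher and 972 sparse, and the median log2 fold change of all 25045 genes was 0.57. SSA_Pos libraries also had more genes detected, 16992 ± 2554 (n = 24) against 13383 ± 1536 (n = 10; permutation test, adjusted p = 0.016). Mucous acinar (-0.39, adjusted p = 0.0135), mucosal antimicrobial (-0.36, adjusted p = 0.0109), mitochondrially encoded (-0.16, adjusted p = 0.000327), unfolded protein response (-0.09, adjusted p = 0.00533) and vesicle marker genes (-0.07, adjusted p = 0.0366) were lower by camera, as was the respiratory chain list, whose median and mean were positive at 0.05 (adjusted p = 0.00724). No list passed with an estimated correlation (adjusted p from 0.282 to 0.861). Mitochondrially encoded and unfolded protein response genes passed by camera without each of the 10 libraries in turn, with medians up to 0.46 and 0.22. The mucous list did not without Lupus replicate 1 (-0.02, 0.25) or 3 (0.08, 0.311) or Rheumatoid_Arthritis replicate 4 (-0.15, 0.149), nor the antimicrobial list without Lupus replicate 5 (-0.21, 0.0672) or Rheumatoid_Arthritis replicate 1 (0.19, 0.0633) or 3 (-0.19, 0.0571). The respiratory chain list did not without Lupus replicate 1 (0.27, 0.324) or 3 (0.37, 0.837) or Rheumatoid_Arthritis replicate 3 (0.18, 0.155) or 4 (0.10, 0.0825). Of these 10 fits vesicle markers passed only in those without Lupus replicate 5 and Rheumatoid_Arthritis replicate 3. Without Lupus replicate 5 edgeR called 2132 genes, and without any 1 of the other 9 libraries 10 to 24. Over the same 25045 genes these counts were 1827 and 8 to 27, so the gene filter does not explain the change. With the first series as the only other libraries edgeR called 0, with 3083 at an unadjusted p under 0.05.

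The SSA_Neg libraries of the third title series stood apart from the other SSA_Neg libraries, which have the same label. Ribosomal protein genes were lower by a median of -1.02 with 48 of 78 called (63 adjusted over the list alone; camera adjusted p = 1.12e-44, adjusted p = 0.344 with an estimated correlation), among them RPL4 (-1.42 ± 0.22, adjusted p = 1.62e-05) and RPL7A (-1.32 ± 0.22, adjusted p = 2.86e-05). The translation factor EEF1G fell as well (-1.37 ± 0.22, adjusted p = 1.67e-05), as did ZNF12 (-2.33 ± 0.37) and DOCK1 (-2.08 ± 0.33). Mitochondrially encoded genes rose, 5 of 9 over all genes and 9 adjusted over the list alone, with a median of 3.45 (camera adjusted p = 7.69e-06, adjusted p = 0.305 with an estimated correlation). MT-CO2 was at 5.35 ± 1.2 (adjusted p = 0.002) and MT-ND1 at 3.45 ± 1.00 (adjusted p = 0.0176). The level of these genes stayed low. Mitochondrially encoded genes took on average 0.0122% of counts in the third series (n = 36), 0.00085% in SSA_Neg of the second (n = 9) and 0.00014% in that of the first (n = 2). TSHR, the thyrotropin receptor (chromosome 14, 80954989 to 81146302), had at least 10 counts in 34 of 36 third-series and 0 of 11 other libraries (adjusted p = 7.61e-06), the platelet gene TUBB1 in 34 and 0 (adjusted p = 2.52e-05), PRR33 in 32 and 0, and the noncoding CASC18 in 30 and 0.

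Gland genes were lower in the third series: 7 of 17 duct genes fell (median -0.98, camera adjusted p = 7.69e-06; KRT7 -1.29 ± 0.32, KRT19 -0.98 ± 0.26) and 3 of 27 serous acinar genes (median -0.67, adjusted p = 0.00029; ODAM -1.80 ± 0.45, ZG16B -1.38 ± 0.38). Scaled with the libraries of all groups, the serous score averaged 3.90 ± 2.19 in the third series (SD, n = 36). It was 4.21 ± 1.84 in SSA_Neg of the second series (n = 9) and 7.57 ± 0.24 in that of the first (n = 2). The score thus differed mainly from those 2 libraries. Respiratory chain genes were lower by -0.67, with 7 of 56 called (adjusted p = 3.74e-12), and 2 of 4 platelet genes rose (adjusted p = 0.0231). Adjusted p was 0.282 for the duct, 0.371 for the platelet, 0.502 for the respiratory chain and 0.774 for the serous list with an estimated correlation. ISG15 stood at 0.39 ± 0.52 without a call. In all 1340 genes were higher and 412 lower.

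Library make-up differed as well. The 10 most abundant genes took 30% of counts in the third series against 8.99% in the other SSA_Neg libraries, and protein-coding genes 68.6% against 92.5% (permutation tests, adjusted p = 2.5e-05 for the latter). Most of this lay in 3 gene models on chromosome 21 of GRCh38 that sit inside 18S ribosomal RNA genes: FP671120.3 (ENSG00000280800, 8210384 to 8211306) in RNA18SN2, FP236383.2 (ENSG00000280614, 8393419 to 8394341) in RNA18SN3 and FP236383.3 (ENSG00000281181, 8437629 to 8438551) in RNA18SN1. They took 23.7% ± 14.4 of counts in the third series (SD, n = 36) and 0.0864% ± 0.107 in the other SSA_Neg libraries (n = 11), and at most 0.407% in any of the 77 libraries outside the third series. Because the third series holds 1 group, its libraries and its donors cannot be told apart, and it stayed out of the comparisons of the first and second series.

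**Figure D4:**
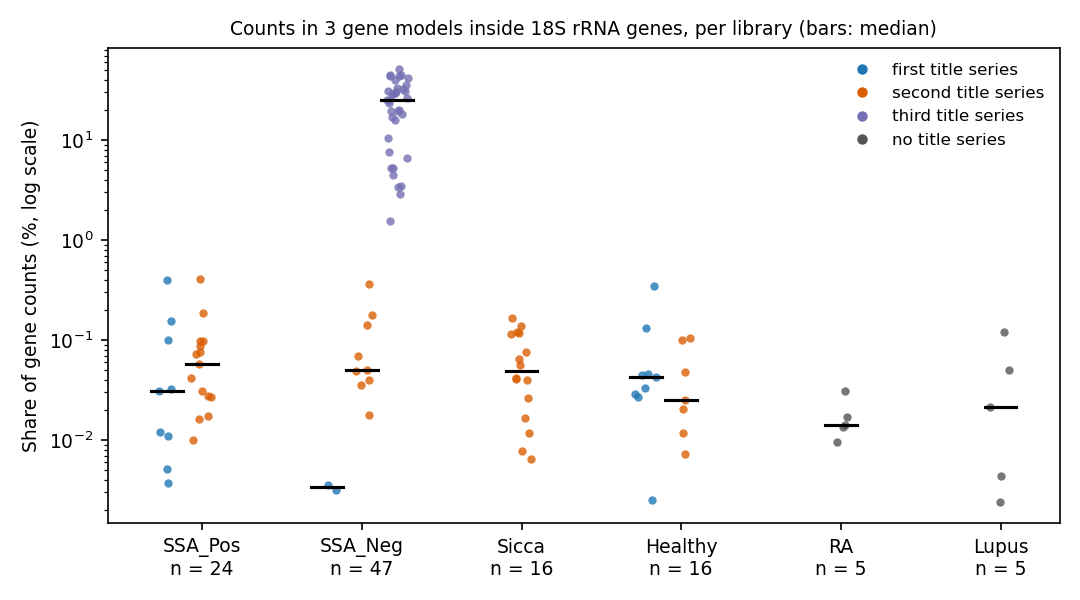
Each point is 1 library, with the share of its gene counts in the 3 gene models inside 18S rRNA genes on the y axis (%, log scale), by group and title series (colour); bars are medians. The 36 third-series libraries lie between 1.55 and 51%, and the other 77 at or below 0.407%.

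Whether the difference of SSA_Pos from Healthy changed between the first and second series was tested gene by gene. No gene was called by edgeR (0 of 18466, with 1668 at an unadjusted p under 0.05), and DESeq2's Wald test called 352. The difference of the interferon score between the series' effects was -1.13 ± 0.86 (second minus first, permutation p = 0.21).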

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

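The tests that weigh explanations for the interferon-stimulated genes were all chosen after the result was seen; the comparison of groups of 4 to 10 libraries for a value far from the others, and the test of title series against each other, were planned.

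Interferon-stimulated genes were higher in SSA_Pos than in Healthy libraries in both title series, with a score difference of 2.34 ± 0.43. Chance can be excluded for the number of members called: 21 with the real groups and 0 in every other of 80 relabellings within series, so that 1 of the 80 was as large. A difference in the first series alone was excluded, since the difference was 1.79 ± 0.42 within the second series. With the log2 spike-in share as a covariate the difference was 1.83 ± 0.43, so a linear effect of that share did not account for all of it. More RNA from neutrophils as the whole cause is argued against by their score, 8.70 ± 0.78 in SSA_Pos and 8.68 ± 0.58 in Healthy. The difference was 2.36 ± 0.41 with that score as a covariate. With the monocyte and macrophage score (2.31 in SSA_Pos and 1.14 in Healthy) it was 1.83 ± 0.40. More RNA from monocytes and macrophages stays open, because a list score measures such RNA only in part and the fit cannot exclude it. A difference that goes with SSA status also stays open. The score was 1.86 ± 0.52 higher in SSA_Pos than in SSA_Neg libraries, and 1.08 ± 0.40 higher with the monocyte and macrophage score (1.27 in SSA_Neg) as a covariate. Both values go the way this explanation predicts, while donor traits that the labels do not give may also differ between these groups. Apart from the neutrophil score and the monocyte and macrophage score, no test addressed the source of this RNA.

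The effect of SSA_Pos against Healthy on 6 gene lists differed between the title series by camera, second minus first. The median difference of log2 fold changes was -1.2 for interferon-stimulated genes (adjusted p = 5.74e-08, adjusted p = 0.684 with an estimated correlation), -0.59 for respiratory chain genes (0.00035 and 0.774), 1.53 for plasma cell genes (0.0215 and 0.774), -0.84 for ribosomal protein genes (2.15e-12 and 0.774), 0.66 for squamous epithelial genes (0.00329 and 0.87) and 2.16 for T and NK cell genes (0.00104 and 0.623). No single gene was called by edgeR (0, with 1668 at an unadjusted p under 0.05 and 352 by DESeq2), and since the real count is 0, all 100 of 100 relabellings had as many by construction (the highest other 80), which says nothing on whether the series differ.

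Of 53 groups of 4 to 10 values tested for a library far from the others, 8 stood out, against about 1 in 20 by chance. Among the 5 Rheumatoid_Arthritis libraries, SNHG26 reached 5.50 log2 CPM in replicate 3 and IL6 6.06 in replicate 2, each with the other 4 at -4.37, the value of no counts. Lupus replicate 1 had 41.8 M counts against 1.82 to 8.80 in the other 4. Lupus replicate 5 had 18.3% of its counts in its 10 most abundant genes against 6.09 to 9.15%, and 89.96% in protein-coding genes against 94.5 to 95.3%. Lupus replicate 3 had a neutrophil score of 2.15 against 7.83 to 9.52 and an NF-kB score of 2.88 against 6.34 to 7.52; without it neither list passed camera in Lupus against Healthy (adjusted p = 0.501 and 0.328). Among the 9 Healthy libraries of the first series, replicate 10 had an interferon score of 1.86 against 3.70 to 4.90; without it the first series still separated, at 6.93 ± 1.97 (n = 9) against 4.27 ± 0.40 (n = 8; exact permutation p = 0.00317).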

How the results depend on the processing

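The covariate fits, the edgeR 4 method, relabelling with voom or the edgeR 4 method, lists and a fixed set of genes with replicates left out, and the fit without 18S models were chosen after the data had been seen; the others were planned. Keeping the older edgeR method for the reported counts was also settled after both had been seen. Counts below are genes called, in the order Sjögren against others, SSA_Pos–Healthy, SSA_Neg–Healthy, SSA_Pos–SSA_Neg, SSA_Pos–Sicca, SSA_Neg–Sicca and Sicca–Healthy (as reported 52, then 102 higher plus 11 lower, 8, 3, 95, 6 and 50). Removing shallow libraries removed none of the 67, so it tests nothing there. The interferon list of SSA_Pos against Healthy, SSA_Neg and Sicca passed camera at the preset correlation in all 5 settings in which lists were retested (DESeq2 size factors, all libraries, the second series alone and both covariates). No filter gave 2534, 3695, 1510, 2528, 4844, 3097 and 2303, DESeq2's Wald test 280, 515, 102, 67, 430, 100 and 166, and the edgeR 4 method 662, 726, 306, 246, 1071, 424 and 641. Voom gave 1.1e+02 (102 higher and 11 lower), 263, 0, 3, 41, 0 and 0; the stricter filter 0, 35, 1, 3, 24, 0 and 0, where fewer genes were tested. All libraries with group alone gave 4205, 1876, 4749, 3593, 1660, 4389 and 1799, which adds the third series and the 10 Rheumatoid_Arthritis and Lupus libraries, drops the term for title series and tests more genes (25045 against 18182), so no single cause can be named. The title prefix as the term gave 46, 108, 0, 0, 55, 1 and 15, the second series alone 8, 4, 0, 0, 98, 20 and 11 with fewer libraries, the spike-in share as a covariate 37, 61, 2, 0, 12, 21 and 86, and genes detected as a covariate 33, 41, 2, 1, 14, 5 and 73. DESeq2 size factors gave 75, 116, 9, 2, 271, 6 and 75. For Rheumatoid_Arthritis, Lupus and SSA_Pos against both (230, 341 and 1320), no filter gave 437, 611 and 103, DESeq2 1864 (157 higher and 1707 lower), 1051 (134 and 917) and 2646, voom 22, 108 and 307, the stricter filter 0, 1 and 63, DESeq2 size factors 240, 308 and 771, the edgeR 4 method 261, 177 and 248, removing shallow libraries 327, 272 and 20, the first series as the other libraries 0, 1 and 0, and leaving the third series out 114, 203 and 1309. Leaving out single replicates gave 193 to 258, 243 to 369 and 10 to 2132. The third series (1752) gave 2712 with DESeq2, 3849 with the edgeR 4 method, 1580 against the second series and 1673 without 18S models; the test between series (0, edgeR) gave 352 with DESeq2, 235 with the edgeR 4 method and 1 with DESeq2 size factors. Of the 82 list tests, 2 passed with an estimated correlation, and 72 to 99 in the other settings. The cause was not tested, except where the setting itself changed the libraries or genes.

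Among the named genes' 155 results, called values stayed called in 783 repeats and lost the call in 296, and 1 reversed; those not called stayed so in 644, passed in 91 and reversed in 2. The reversals were ISG15 in SSA_Neg against Healthy (-0.42 in the second series alone), SNHG26 in Rheumatoid_Arthritis (0 without Rheumatoid_Arthritis replicate 3, up to 11.82 without another library) and IL6 there (-7.94 without Rheumatoid_Arthritis replicate 2, up to 4.35). SNHG26 and IL6 are fitted values of genes with almost no counts, and each rests on the library left out; the cause was not tested for ISG15. No paired analysis was possible because the labels give no replicate numbers shared by groups. What depth limits was not tested by thinning; of the calls reported, 58 in SSA_Pos against Healthy and 316 of 341 in Lupus lacked 10 counts in at least 50% of the libraries on either side.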

Other observations

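Relabelling with the method of the reported counts and the camera test of B cell genes were planned; the other tests in this part, relabelling with voom or the edgeR 4 method among them, were chosen after the result was seen.

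Correlations between libraries were taken after the mean of each group within its title series was subtracted from both values. Across the 67 libraries of the first and second series, the interferon score rose with the neutrophil score (r = 0.44, rho = 0.37, permutation p = 0.00025 and 0.00226, adjusted p of r = 0.0005 over 6 relations). It held in the first (r = 0.75, n = 20) and second series (r = 0.32, n = 47) and was 0.33 without the 2 farthest libraries. A relation with the serous acinar score was not shown (r = 0.23, rho = 0.20, permutation p = 0.0654 and 0.103; within series r = 0.32 and 0.18; 0.19 without the 2 farthest libraries). The serous acinar score fell with the log2 spike-in share (r = -0.45, rho = -0.45, permutation p = 0.00011 and 0.00013, adjusted p of r = 0.00033; r = -0.52 and -0.43 within series; -0.49 without the 2 farthest). B cell genes passed camera in no comparison; their median in SSA_Pos against Healthy was 1.56 over 6 genes (adjusted p = 0.156).

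Third-series SSA_Neg libraries differed from the other SSA_Neg libraries in 1752 genes, and chance can be excluded, with 120 in the highest of the other 99 splits (1 of 100 as large). The counts of the 3 gene models inside 18S rRNA genes were excluded as the whole cause, since 1673 genes were called without them. TMM scaling already limits the weight of a few dominant genes, so little change was likely. Dropping these rows does not test a wider difference in library make-up that they may mark. A difference between library batches in noncoding RNA content stays open: 49.4% of the genes called higher were not protein coding, against 17.8% of those tested and 11.1% of those called lower. A difference between donors cannot be told apart from it, because the third series holds 0 libraries of other groups.

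More genes were called higher than lower in SSA_Pos against Sicca (72 and 23), and the choice of library scaling may account for this, since 33.9% of the called genes were higher with DESeq2 size factors (92 and 179). Scaling is not the only setting that changes the balance: it was 177 and 253 with DESeq2's Wald test, which has its own size factors, but with the reported scaling also 11 and 13 with the stricter filter and 6 and 6 with the spike-in share as a covariate, against 37 and 4 with voom and 86 and 12 in the second series alone. More genes detected in SSA_Pos libraries stays open: with their number as a covariate 64.3% of the called genes were higher (9 and 5), too few to decide. The interferon-stimulated genes of that comparison had a median of 1.52 with 11 called as reported, 1.29 with 0 called by edgeR (19 adjusted over the list alone) once genes detected was a covariate, and 1.33 with 10 called with DESeq2 size factors, so the median stayed above 1 in each while the calls over all genes ended with the covariate.

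Relabelling the libraries within title series 80 times gave these bounds on chance for the reported counts. The labels of SSA_Pos, SSA_Neg, Sicca and Healthy were shuffled together, here and with the other tools below. A pair of groups is thus weighed against no difference among any of these groups, and not against no difference within the pair. Verdicts are at 1 in 20 for each comparison, without adjustment over the comparisons. At that bound chance can be excluded for Sjögren against others (52 called, highest other 17, 1 of 80 as large), SSA_Pos against Healthy (102 higher plus 11 lower, 79 and 1) and SSA_Pos against Sicca (95, 53 and 1). It can be excluded only narrowly for Sicca against Healthy (50, 89 and 2), where another split called more genes than the real groups. It cannot for SSA_Neg against Healthy (8, 26 and 9), SSA_Pos against SSA_Neg (3, 52 and 32), SSA_Neg against Sicca (6, 106 and 15) or the correlation of fold changes between SSA_Pos against Healthy and SSA_Neg against Sicca (0.018, 0.139 and 65; for correlations the splits as large are counted by absolute value, and the highest other is the highest positive one). Some of these splits called several times the real number (106 against 6), which points to a structure of the samples. Differences among the groups shuffled together may be part of that structure. No test addressed what it is, and the edgeR test also made false calls on simulated counts (10 of 37). Relabelling the SSA_Pos, Healthy, Rheumatoid_Arthritis and Lupus libraries 80 times gave 13 of 80 as large for Rheumatoid_Arthritis against Healthy (230, highest other 367) and 4 of 80 for Lupus against Healthy (341 and 406), so chance cannot be excluded for either; for SSA_Pos against both diseases it was 3 of 80 (1320 and 1797), so chance can be excluded there at 1 in 20 for this fit, which has no term for title series, while at least 1 other split called more. That count does not hold in other fits: with the first series as the only other libraries edgeR called 0 (3083 at an unadjusted p under 0.05), and without any 1 of 9 of the 10 disease libraries 10 to 24.

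Other tools did not agree on all of these. With voom and 60 relabellings chance can be excluded for Sjögren against others (102 higher plus 11 lower, highest other 3, 1 of 60 as large), SSA_Pos against Healthy (263, 17 and 1), SSA_Pos against Sicca (41, 12 and 1) and the correlation (0.203, 0.201 and 2 by absolute value, so the other split was negative), and not for SSA_Pos against SSA_Neg (3, 194 and 5). Voom called 0 genes in SSA_Neg against Healthy, SSA_Neg against Sicca and Sicca against Healthy, where the highest other splits called 23, 39 and 22. With the edgeR 4 method and 60 relabellings chance can be excluded at the same bound for Sjögren against others (662, 764 and 2), SSA_Pos against Healthy (726, 772 and 2) and SSA_Pos against Sicca (1071, 989 and 1). For Sjögren against others and SSA_Pos against Healthy another split called more genes than the real groups, so chance is excluded there only narrowly. It cannot for Sicca against Healthy (641, 1003 and 6), SSA_Neg against Healthy (306, 770 and 19), SSA_Pos against SSA_Neg (246, 1413 and 20), SSA_Neg against Sicca (424, 1155 and 17) or the correlation (0.034, 0.112 and 35 by absolute value). The exclusion of chance for Sicca against Healthy thus holds for the reported method alone, and the verdict on the correlation depends on the tool. The median of the other splits was 298, 302 and 388 genes with the edgeR 4 method for the first 3 of these, and 1, 1 and 4 with the older method, so part of what the edgeR 4 method calls arises without the groups. Of the interferon-stimulated genes in SSA_Pos against Healthy voom called 35 and at most 5 in the other splits, and the edgeR 4 method 30 and at most 10.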
